A study of Rattus norvegicus with 38 samples.

How the data were processed

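Kidney RNA of 38 rats in 4 groups was sequenced. Libraries were made with the QuantSeq 3' mRNA-Seq FWD kit from 500 ng of total RNA, per the labels' protocols, so that reads come from the 3' ends of transcripts and gene length does not scale the counts. The submitters' processing notes name Salmon 1.4.0, edgeR 3.40.2 and DESeq2, with no version for the last and with no order or role. The genome build and the annotation were not given in the sources used here. The deposited table holds log2 values that the authors scaled by library size and variance-stabilised, as the name given to the table and its values show. It has 30207 rows of Ensembl rat gene identifiers and 38 columns, and 2 further rows that hold the sample and group names and were left out. Each column was matched to its sample by the library name in the labels. Columns of another series numbered 0.

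The lowest value of the table, 4.31634, was shared by all libraries and is the value of a count of 0. It makes up 44.26% of the values, and 8009 genes stand at it in every library. Inverting the stabilising curve from this value gave numbers that are whole multiples of a step of each library. All values of up to 10000 reads came out within 0.05 of a whole read (100% in each library), so the depth of each library was taken as the sum of these recovered reads. Depth lay between 4120902 and 7728848 reads, and 3 reads were taken as the upper 95% limit of a count of 0. The libraries carry no molecular identifiers that were used here, so limits from counts cover counting error only.

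The groups were taken from the titles of the samples. The table calls the columns animals, and no label gives a batch, a litter or a pairing. The library names are numbered in the order of the groups, so a batch that followed this order could not be told apart from treatment. No 2 libraries were alike within sampling noise: the lowest chi-square per degree of freedom over 703 pairs was 4.11, and 0 columns were identical.

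Tests were fitted on the deposited log2 values with limma 3.58.1 in R 4.3.3, as chosen before the data were examined. Genes were kept when their mean over the 38 animals was at least 1 log2 unit above the lowest value, that is 5.32. This left 12599 genes, which held at least 99.43% of the reads of every library. The means of the 4 groups were fitted in a single model, with eBayes using a trend and robust estimation, and 7 contrasts were tested with Benjamini-Hochberg adjustment within each and a threshold of 0.05. Fold changes are differences on the deposited scale, which is compressed at low counts and understates the change of genes with few reads. Single measures of libraries were compared by two-sided permutation tests, exact where vehicle entered and with 100000 resamples otherwise, adjusted over the 6 comparisons of a measure. Fold changes of comparisons that share no animal were correlated across genes, with a jackknife SE over animals. The chance range came from 100 simulations in which all groups had the vehicle means and the residuals of animals were reassigned. For the single treatments, which share the vehicles, the correlation was also taken over the 70 splits of the vehicles, and, as an alternative added after the data were seen, with the same 4 vehicles in both comparisons. The splits were also used for the overlap of calls with the combination, again after the data were seen.

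The fit was tested on 20 simulated tables in which 200 of the 12599 genes were changed in the combination. Against vehicle, 9.3% of genes changed by 0.25 log2 units were called, 67.8% at 0.5, 96.1% at 1 and 99.9% at 2, with 3.7 false calls on average. For the interaction the shares were 2.1%, 35.2%, 87.9% and 99.4%, with 5.25 false calls. These shares hold for 200 changed genes. The adjustment is stricter where fewer genes change, so the shares would be lower there, and higher where more genes change.

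No table used here pairs the identifiers with gene names: 0 of the 30207 identifiers were found in the reference table of gene names. The 29 gene lists, the panel of named genes, the set tests and the relations between lists across animals that had been fixed before the data were examined were therefore not run. The rule for named genes took, per comparison, the called genes with a symbol that had the largest fold changes in each direction. Without symbols, its ranking was applied to the identifiers of the combination against vehicle, with only the first 2 in each direction taken, a choice made after the data were seen. No GC content or gene length was used.

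Alternatives fixed before the data were examined were median-centred libraries, quantile normalisation, no filter on low values and a filter at 2 log2 units. Further ones were no trend and no robust estimation, a fit of only the groups compared, array weights for libraries, each animal left out in turn, and a threshold of 1.5-fold beside the adjusted p. Alternatives added after the data were seen were 3 libraries of lowest array weight left out, log2 depth as a covariate, the share of reads in the 10 most abundant genes as a covariate, and limma's voom on the recovered reads with the authors' scaling of the libraries. Each comparison was also repeated on 99 other random assignments of its animals to groups of the same sizes.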

Results

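Kidney RNA of 38 rats was profiled by 3' end sequencing after 7 weeks of treatment, in a series on injury of the glomerulus and the tubule. Vehicle was given to 8 animals. Anti-Fx1A, an antiserum against a brush border fraction of the rat proximal tubule that is used to induce Heymann nephritis, was given to 10 animals at 2.5 mL/kg. L-NAME, an inhibitor of nitric oxide synthase, was given to 10 animals at 20 mg/kg per day. A combination of both was given to 10 animals, with L-NAME at 20 mg/kg per day and anti-Fx1A at the lower dose of 2.0 mL/kg. Comparisons of the combination with a single treatment therefore hold a difference in anti-Fx1A dose as well. Animals are named below by their group and their number in the series, 1 to 38. These numbers run in the order of the groups, so an effect of that order cannot be told apart from treatment.

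The libraries held between 4120902 and 7728848 reads. Mean depth was 5736477 ± 1042443 reads (SD, n = 8) with vehicle, 6012765 ± 1083279 (n = 10) with anti-Fx1A, 5873873 ± 786531 (n = 10) with L-NAME and 6236273 ± 505171 (n = 10) with the combination. No comparison of depth between groups gave a permutation p under 0.204 (exact where vehicle entered, two-sided). At least 1 read was found for 16550 genes on average with vehicle, 16817 with anti-Fx1A, 16955 with L-NAME and 16966 with the combination. The 10 most abundant genes took 30.3 ± 1.46% of the reads with vehicle (n = 8), 29.7 ± 7.56% with anti-Fx1A, 28.4 ± 4.84% with L-NAME and 28.7 ± 5.22% with the combination (n = 10 each). No comparison of these shares between groups passed (lowest permutation p 0.302), and their SD was larger in each treated group than with vehicle. Genes are known here by their Ensembl identifiers alone, so the comparisons are described by the number, size and direction of the changes and by 4 genes under their identifiers.

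The leading principal component of the 12599 genes tested held 31.6% of the variance and ordered the group means from vehicle over anti-Fx1A and L-NAME to the combination. Its mean was 18.02 ± 12.9 with vehicle (SD, n = 8), 9.17 ± 12.4 with anti-Fx1A, -3.28 ± 20.8 with L-NAME and -20.3 ± 11.5 with the combination (n = 10 each). The combination lay apart from vehicle and from anti-Fx1A (adjusted p = 0.000206 each, exact and sampled permutation test, two-sided). L-NAME lay apart from vehicle (adjusted exact permutation p = 0.0366). The remaining comparisons did not pass, with adjusted permutation p of 0.0562 for the combination against L-NAME, 0.143 for anti-Fx1A against L-NAME and 0.157 for anti-Fx1A against vehicle. The second component held 16.3% of the variance and no comparison of groups on it passed (lowest adjusted permutation p 0.501).

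**Figure D1:**
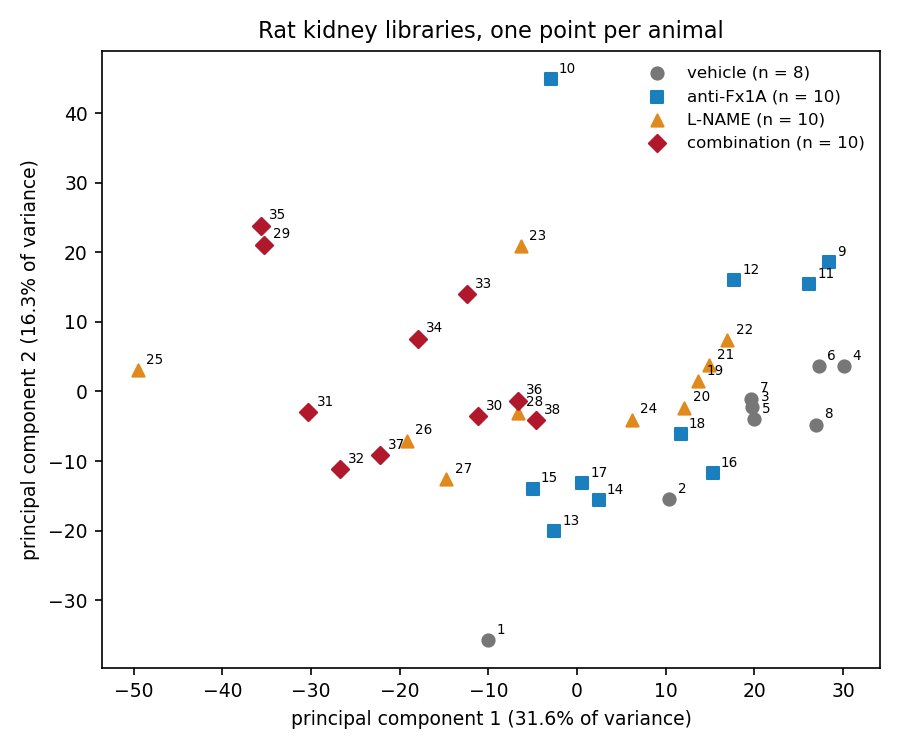
Position of each of the 38 kidney libraries on the first principal component (x axis, 31.6% of variance) and the second (y axis, 16.3%), in component units, with symbols for the 4 groups and the animal number beside each point. The combination animals lie between -35.7 and -4.61 on the first component, and 7 of the 8 vehicle animals lie above 10; vehicle animal 1, anti-Fx1A animal 10 and L-NAME animal 25 stand at the edges of the plot.

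Anti-Fx1A alone was compared with vehicle to show what the antiserum did by itself. The genes called were few, and most of them were higher. Of the 12599 genes tested, 117 were higher and 22 lower with anti-Fx1A (limma, adjusted p under 0.05). The median log2 fold change was 0.50 among the genes that rose and -0.43 among those that fell. A change of at least 1.5-fold was reached by 34 of the higher and 2 of the lower genes, and at least a doubling by 6 and 0. At an unadjusted p under 0.05, 1837 genes passed, where 630 would on average by chance. Genes vary together, so the number that passes by chance can lie far from 630, and its range was not measured. The count of 139 depended on single animals. Without anti-Fx1A animal 9 it was 294, without animal 16 it was 241, without animal 12 it was 89 and without animal 15 it was 85. It was 624 when noisier libraries were given less weight, 260 with the share of the 10 most abundant genes as a covariate and 50 when only these groups were fitted.

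L-NAME alone was compared with vehicle to show what inhibition of nitric oxide synthase did by itself. It changed 14.1% of the genes tested, in both directions: 996 were higher and 784 lower than with vehicle (limma, adjusted p under 0.05). The changes were small in most genes, with a median log2 fold change of 0.45 among the higher and -0.38 among the lower. At least 1.5-fold was reached by 249 of the higher and 125 of the lower genes, and 9 in each direction at least doubled or halved. The genes that fell were more abundant in vehicle kidney than those that rose, with median vehicle values of 8.32 and 7.24 on the log2 scale against 7.10 over all genes tested. Most genes called for anti-Fx1A also changed with L-NAME in the same direction. Of the 117 genes higher with anti-Fx1A, 84 were higher with L-NAME, where independent lists of these lengths would share 9.25. Of the 22 lower genes 21 were lower, where independent lists would share 1.37, and no gene was called in opposite directions. The fold changes of the single treatments correlated across genes at r = 0.779 (jackknife SE 0.0962), but both rest on the same vehicle animals. Simulated unchanged groups against those vehicles gave r = 0.566 on average, with a range of 0.0676 to 0.894. The covariance was 0.0364, within the simulated range of 0.000869 to 0.0423, and exceeded the simulated mean of 0.0119 by 0.0245. With the vehicles split so that each comparison used 4 of them, r averaged 0.470 over 70 splits, against 0.811 when both comparisons used the same 4. The covariance averaged 0.0263 over those splits, with a range of 0.0111 to 0.0335, and so stayed positive when no vehicle was shared. No simulation without effects was run for the splits. The shared calls averaged 0.186 over those splits, against 105 with all vehicles. The simulation gave 0, which is no measure for the 105, since only 5 of 100 simulations called any gene for anti-Fx1A and 1 for L-NAME. Where genes were called, the count reached 573 for anti-Fx1A, above the 139 found, and 615 for L-NAME. With 4 vehicles per comparison the calls themselves averaged 4.29 for anti-Fx1A and 539 for L-NAME, and part of the overlap may come from the shared vehicle animals.

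**Figure D2:**
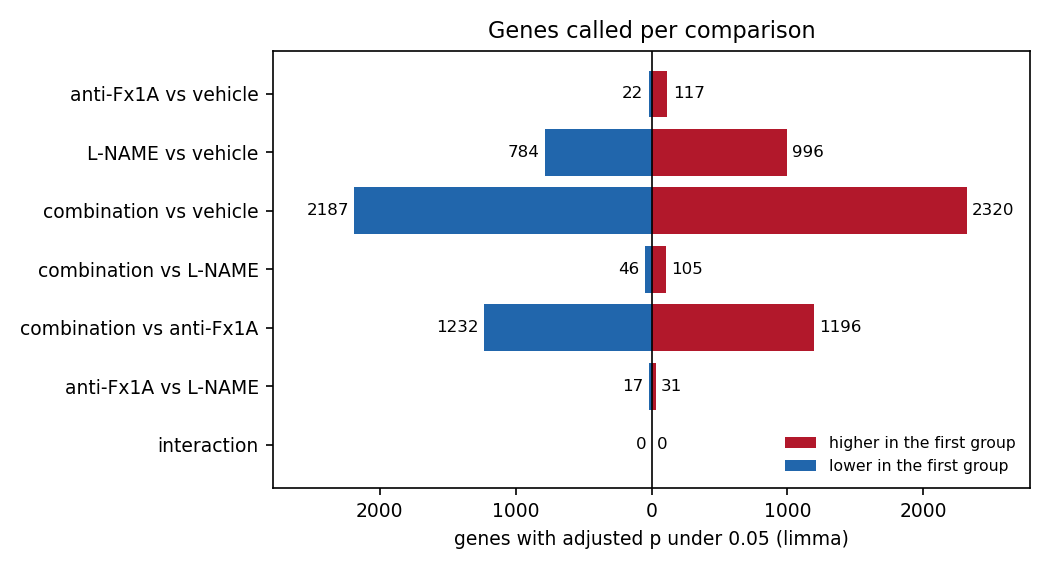
Number of genes called at an adjusted p under 0.05 by limma (x axis) in each comparison (y axis), with genes higher in the first-named group to the right of 0 and lower genes to the left. The combination against vehicle gave 2320 higher and 2187 lower genes, L-NAME against vehicle 996 and 784, anti-Fx1A against vehicle 117 and 22, and the interaction 0.

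The combination was compared with vehicle to show the response to both treatments together. It changed 35.8% of the genes tested, with 2320 higher and 2187 lower (limma, adjusted p under 0.05). Over all 12599 genes the median absolute log2 fold change was 0.21, against 0.15 for L-NAME and 0.10 for anti-Fx1A alone. Among the called genes the medians were 0.46 and -0.43, of which 130 at least doubled and 120 fell to no more than a ratio of 0.5. At least 1.5-fold was reached by 761 of the higher and 612 of the lower genes. Many genes called for a single treatment were called here as well. Of the genes called for L-NAME, 921 of 996 higher and 678 of 784 lower genes were called in the same direction in the combination, where independent lists would share 183 and 136. Of those called for anti-Fx1A, 103 of 117 higher and 21 of 22 lower genes were, where independent lists would share 21.5 and 3.82. These comparisons share the vehicle animals too, which raises such overlaps. Simulations without effects gave 0 shared calls, but 0 of 100 called any gene for the combination, so this does not measure how far the shared vehicles raise the overlap. With the vehicles split so that each comparison used 4 of them, 539 genes on average were called for L-NAME and 386 of these also for the combination in the same direction (71.6%), where independent lists would share 63.6. For anti-Fx1A the split left 4.29 calls on average, of which 3.37 were shared.

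Among the genes called in the combination, ENSRNOG00000007243 and ENSRNOG00000020039 had the largest increases on the deposited scale, and ENSRNOG00000033152 and ENSRNOG00000029512 the largest decreases. They were chosen for their difference between these combination and vehicle animals. Their values in comparisons that use those animals tend to be inflated by the choice. ENSRNOG00000020039 had a mean of 5.53 ± 0.48 with vehicle (SD, n = 8), 6.38 ± 0.77 with anti-Fx1A, 6.75 ± 0.72 with L-NAME and 8.14 ± 0.79 with the combination (n = 10 each). It was 2.61 log2 units above vehicle in the combination (SE 0.33, limma adjusted p = 4.53e-07), and all 10 combination animals lay above the highest vehicle animal. It also exceeded L-NAME alone by 1.396 (adjusted p = 0.0183) and anti-Fx1A alone by 1.77 (adjusted p = 0.000361). L-NAME alone raised it by 1.21 (adjusted p = 0.0104), while the 0.84 with anti-Fx1A alone did not pass (adjusted p = 0.194). Median reads for it were 13.5, 37, 67.5 and 290.5 in the same order of groups.

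ENSRNOG00000007243 differed widely between animals of a group. Its mean was 5.61 ± 0.98 with vehicle (SD, n = 8), 6.55 ± 1.78 with anti-Fx1A, 7.07 ± 2.31 with L-NAME and 8.30 ± 2.22 with the combination (n = 10 each), with median reads of 9, 28.5, 26 and 275.5. Among the comparisons it was called only in the combination against vehicle (log2 fold change 2.69, SE 0.91, limma adjusted p = 0.0201), and 7 of 10 combination animals lay above the vehicle range. A test of the recovered reads with voom, chosen after the data were seen, did not call it, although the log2 fold change was larger there, at 3.93 (adjusted p = 0.108, within 0.00946 to 0.108 over 29 alternatives).

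ENSRNOG00000033152 and ENSRNOG00000029512 were each read in some animals of a group and not in others, in vehicle animals as well, so that no treated animal lay below the vehicle range. ENSRNOG00000033152 had 0 reads in 1 of 8 vehicle animals, 0 of 10 anti-Fx1A animals, 3 of 10 L-NAME animals and 7 of 10 combination animals. Its median was 1287.5 reads with vehicle, 768 with anti-Fx1A, 342 with L-NAME and 0 with the combination. The log2 fold change of the combination was -4.30 against vehicle (SE 0.92, limma adjusted p = 0.000479) and -4.004 against anti-Fx1A (adjusted p = 0.00242). Neither was called with voom, although the log2 fold changes were larger there. Against vehicle voom gave -7.50 (adjusted p = 0.0703, within 3.51e-06 to 0.0703 over 29 alternatives) and against anti-Fx1A -7.78 (adjusted p = 0.0854, within 0.000417 to 0.0854 over 31). Against L-NAME alone it was -2.06 (adjusted p = 0.237), and L-NAME against vehicle gave -2.24 (adjusted p = 0.0984). The difference from L-NAME alone was called with library weights (-2.46, adjusted p = 0.0364) and without vehicle animal 1, anti-Fx1A animal 10 and L-NAME animal 25 (-2.42, adjusted p = 0.0394), within 0.0364 to 0.603 over 31 alternatives. L-NAME against vehicle was called in the same fits (-2.48, adjusted p = 0.0203, and -2.66, adjusted p = 0.0285, within 0.0129 to 0.194 over 29 alternatives). ENSRNOG00000029512 had 0 reads in 2 of 8 vehicle, 4 of 10 anti-Fx1A, 5 of 10 L-NAME and 10 of 10 combination animals. For the whole combination group, 3 reads were taken as the upper 95% limit of a count of 0. At that limit ENSRNOG00000029512 was at least 481-fold lower there than the vehicle mean. It was at least 538-fold lower than the anti-Fx1A mean and at least 160-fold lower than the L-NAME mean. These bounds cover counting error only and not the spread between animals, and the difference from L-NAME alone was not called (log2 fold change -1.30, limma adjusted p = 0.335, within 0.127 to 0.522 over 30 alternatives). On the deposited scale the difference from vehicle was -2.49 (limma adjusted p = 0.00552).

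The call of ENSRNOG00000029512 against anti-Fx1A alone (log2 fold change -1.93, limma adjusted p = 0.0365) was less firm, and its adjusted p ran from 0.00847 to 0.118 over 30 alternatives. It did not pass without anti-Fx1A animal 9 (-1.62, adjusted p = 0.0848), 10 (-1.60, 0.0667), 11 (-1.71, 0.0751) or 12 (-1.79, 0.0635). It was lost with the log2 fold change still at -1.93 without combination animal 29 (0.0505), 31 (0.0523) or 35 (0.0531) and without the filter on low values (0.0558). With library weights it was -1.23 (0.118), and with voom it was larger, at -4.59 (0.117). ENSRNOG00000033152, in contrast, passed for L-NAME against vehicle without vehicle animal 1, which had 0 reads (log2 fold change -3.02, adjusted p = 0.0129, within 0.0129 to 0.194 over 29 alternatives). ENSRNOG00000007243 passed for the combination against anti-Fx1A without anti-Fx1A animal 10 (2.24, adjusted p = 0.0459), with library weights (1.94, adjusted p = 0.0457) and without the 3 libraries of lowest weight (2.24, adjusted p = 0.0282), within 0.0282 to 0.277 over 31 alternatives.

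**Figure D3:**
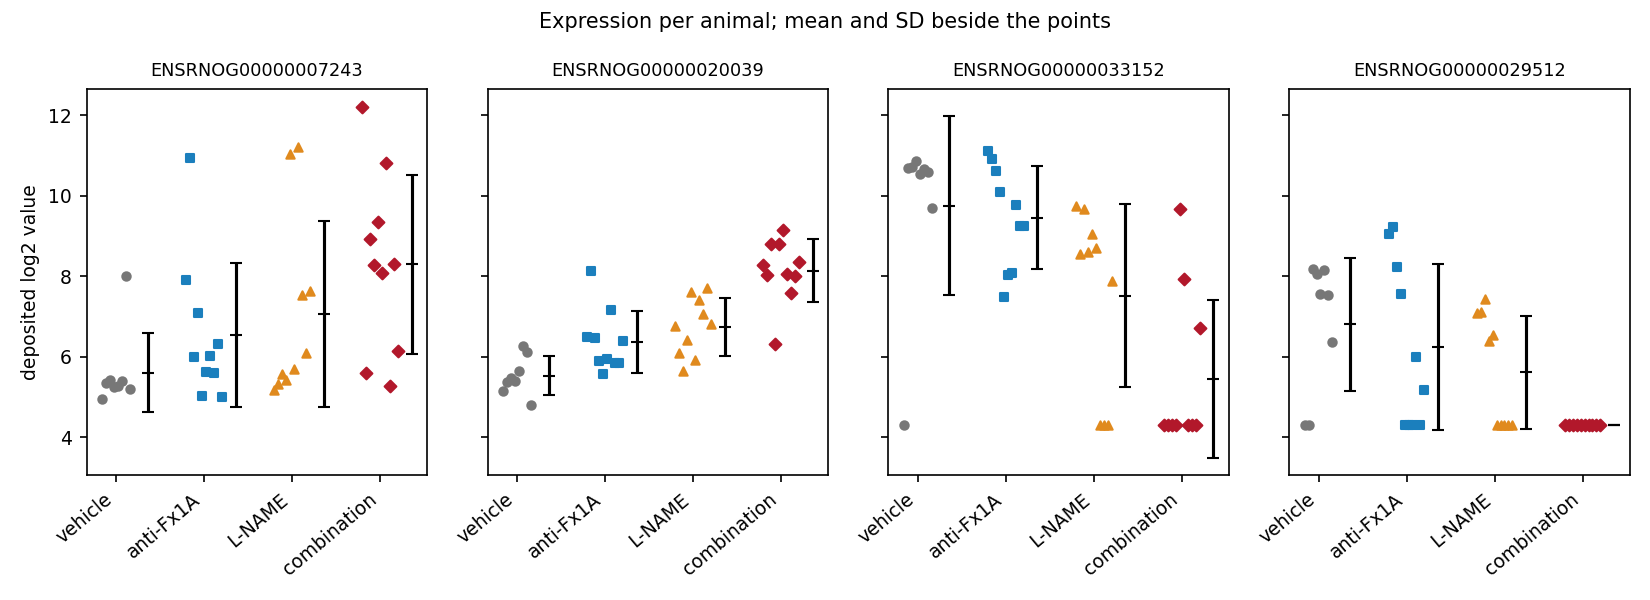
Deposited log2 value (y axis) of 4 genes in each animal of the 4 groups (x axis), with the mean and SD beside the points; 4.32 is the value of a count of 0. All 10 combination animals lie above the vehicle range for ENSRNOG00000020039, while ENSRNOG00000033152 and ENSRNOG00000029512 stand at 4.32 in 7 and 10 combination animals and in 1 and 2 vehicle animals.

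The combination was compared with anti-Fx1A alone to show what L-NAME added in the presence of the antiserum. It changed 19.3% of the genes tested, with 1196 higher and 1232 lower (limma, adjusted p under 0.05) and median log2 fold changes of 0.39 and -0.42. Of these, 23 at least doubled and 40 fell to no more than a ratio of 0.5. This comparison shares no animal with L-NAME against vehicle, and the responses ran in the same direction. Of the 996 genes raised by L-NAME alone, 94.9% were above anti-Fx1A in the combination and 506 were called so, where independent lists would share 94.5. Of the 784 lowered by L-NAME alone, 89.3% were below and 305 were called, where independent lists would share 76.7. A single gene was called in opposite directions. Genes chosen by their call in a comparison had larger fold changes there than in the other, whichever was used to choose them. The median log2 fold change of genes raised by L-NAME alone was 0.45 there and 0.29 in the presence of anti-Fx1A, and that of the lowered genes -0.38 and -0.22. Genes called in the presence of anti-Fx1A had medians of 0.39 and -0.42 there, and of 0.31 and -0.25 for L-NAME alone. These medians therefore do not show a weaker response in either. Across all genes tested the fold changes of L-NAME without and with anti-Fx1A correlated at r = 0.691 (jackknife SE 0.149). In 100 simulations without effects r lay between -0.656 and 0.518. Genes are not independent replicates, so no p is given for r.

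The combination was compared with L-NAME alone to show what the antiserum added, at its lower dose. Few genes were called: 105 were higher and 46 lower (limma, adjusted p under 0.05), with median log2 fold changes of 0.59 and -0.50, and 8 higher genes at least doubled. At an unadjusted p under 0.05, 1968 genes passed, where 630 would on average by chance, with a range that was not measured. The 117 genes raised by anti-Fx1A alone lay above L-NAME in 88% of cases, with a median log2 fold change of 0.13 here and 0.50 for anti-Fx1A alone, the comparison that chose them. The 105 genes chosen as higher here had medians of 0.59 here and 0.21 for anti-Fx1A alone, where 89.5% had the same sign. The 46 genes chosen as lower here had a median of -0.50 here and -0.020 for anti-Fx1A alone (quartiles -0.157 and 0.062), where 58.7% had the same sign. The lists of 117 and 105 genes shared 5, where independent lists would share 0.975, and of the 22 genes lowered by anti-Fx1A alone 0 were called lower here. Across all genes tested the fold changes of anti-Fx1A without and with L-NAME correlated at r = 0.352 (jackknife SE 0.21), inside the range of -0.625 to 0.636 in simulations without effects. The number of genes called against L-NAME alone rested on L-NAME animal 25, which had the lowest position of all animals on the first component, at -49.5. Without it 640 genes were called in place of 151, and 1155 without it, vehicle animal 1 and anti-Fx1A animal 10. Without L-NAME animal 26 the count was 235 and without combination animal 36 it was 233. It fell to 47 without L-NAME animal 22, 62 without 21, 67 without 19 and 73 without 24. It fell to 77 without combination animal 34, 78 without 31, 88 without 35 and 89 without 37. It was 990 with library weights, 341 with the share of the 10 most abundant genes as a covariate and 95 without the filter on low values.

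**Figure D4:**
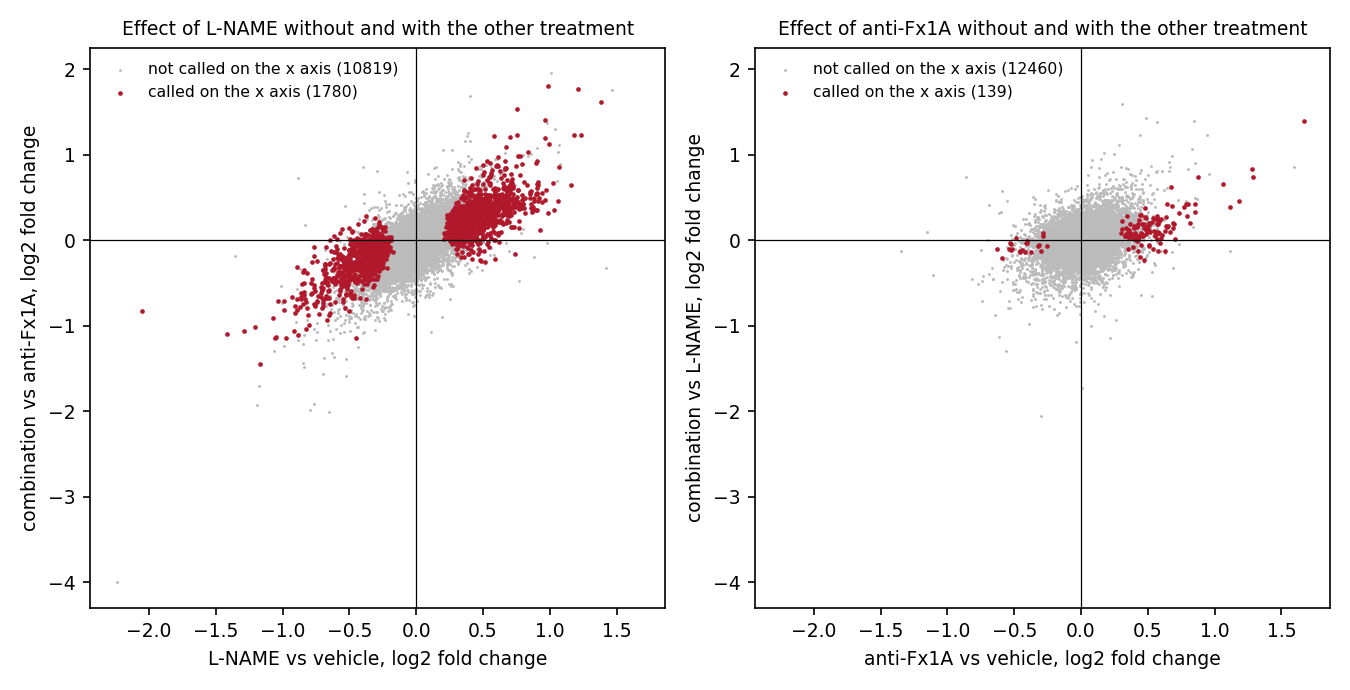
Log2 fold change of each of the 12599 genes tested for L-NAME without (x axis) and with (y axis) anti-Fx1A on the left, and for anti-Fx1A without (x axis) and with (y axis) L-NAME on the right, with genes called in the x axis comparison in red. The x and y values of a panel come from different animals, and r across genes was 0.691 on the left and 0.352 on the right.

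The single treatments differed from each other in 31 genes higher and 17 lower with anti-Fx1A than with L-NAME (limma, adjusted p under 0.05), 1 of which at least doubled. At an unadjusted p under 0.05, 1389 genes passed, where 630 would on average by chance, with a range that was not measured. Other assignments of these animals to groups gave up to 1978 calls at an adjusted p under 0.05. The excess over 630 therefore does not by itself show a difference. The count of 48 fell to 20 without L-NAME animal 25, 21 without 27, 25 without 23, 27 without 26 and 31 without 28. It fell to 26 without anti-Fx1A animal 9 and to 29 without animal 14 or animal 17. It was 22 when only these groups were fitted, 27 without the filter on low values and 77 with the share of the 10 most abundant genes as a covariate.

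Whether the combination departed from the sum of the single treatments was tested as an interaction, which also holds the lower antiserum dose in the combination. No gene was called by limma, with a lowest adjusted p of 0.0505, and 0 were called by voom. At an unadjusted p under 0.05, 1102 genes passed, where 630 would on average by chance, with a range that was not measured. In simulated tables a true departure of 0.5 log2 units was called in 35.2% of changed genes and one of 1 log2 unit in 87.9%, so departures of 0.5 log2 units or less would often be missed. The count was not 0 in every fit. It was 15 without anti-Fx1A animal 10, 6 without L-NAME animal 25 and 5 without L-NAME animal 26. It was 3 without combination animal 32, 2 without anti-Fx1A animal 11, L-NAME animal 21 or combination animal 29, and 1 without vehicle animal 7 or 8. It was 37 with library weights and 41 without L-NAME animal 25, vehicle animal 1 and anti-Fx1A animal 10. The fit of all animals, on other assignments to groups, gave up to 375 interaction calls, so counts of this size can arise by chance. Most of the calls were negative, that is, the combination lay below the sum of the single treatments. For a gene that falls with treatment this is a larger fall, so the sign alone does not show a weaker response. Of the 37, 33 were negative and 4 positive, and 14.6% of the 41 were positive. All 15 calls without anti-Fx1A animal 10 and all 6 without L-NAME animal 25 were negative.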

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

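The tests of the share of abundant reads on the second component and of genes read in only some animals were chosen after those results had been seen, and the alternatives without 3 libraries and with covariates were added after the data were seen.

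In 36 sets of animals (4 groups by 9 measures), 3 animals stood far from the rest of their group. Chance gives about 1 in 20 sets, so a number of this size is not remarkable among 36. ENSRNOG00000007243 stood at 8.02 in vehicle animal 7, with the next vehicle animal at 5.41. It stood at 10.95 in anti-Fx1A animal 10, with the next at 7.90. ENSRNOG00000033152 stood at 4.32, a count of 0, in vehicle animal 1, with the next at 9.70.

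Many more genes were called against vehicle for the combination (4507) than for anti-Fx1A alone (139), although the antiserum dose was lower in the combination. Leaving out the 3 libraries of lowest weight did not remove this: anti-Fx1A then gave 201 calls and the combination 5318. Animal 10 was the only anti-Fx1A animal left out there, so that fit does not test a wide spread among the others. In the reported fit, however, all groups share the same estimate of the spread of a gene. The median SE was 0.1105 in both comparisons. A wide spread among anti-Fx1A animals thus enters both alike, which argues against it as the cause of the difference in that fit. With library weights, which lower the influence of every noisier library, anti-Fx1A gave 624 calls and the combination 5657. With log2 depth as a covariate the combination gave 4236 calls, and with the share of abundant reads 4964, so neither removed the pattern. L-NAME, which the design adds in the combination, may account for it as a hypothesis, since L-NAME alone gave 1780 calls. The part that rests on both treatments together stays open: the interaction gave 0 calls in the reported fit, but 41 without the 3 libraries, 37 with library weights, 4 with the share and 2 with depth as a covariate.

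The second principal component spread the anti-Fx1A animals, with animals 9 to 12 between 15.5 and 44.9 and animals 13 to 18 between -20.1 and -6.18. The former also had fewer reads, 4434855 to 5228067 against 6454754 to 7119831, and the labels give no batch. Within anti-Fx1A the component correlated with log2 depth at r = -0.799, but r was -0.153 in L-NAME and -0.16 in the combination. Depth thus went with the component only in anti-Fx1A. There, animals 9 to 12 had reads in more genes, 16830 to 17283, than animals 13 to 18, 16478 to 16825. Fewer reads by themselves would give fewer such genes, which argues against depth as the sole cause in anti-Fx1A. With the 10 most abundant genes left out of the component, its r with their share, centred within group, was -0.759, and scaling does not account for it, since a component after quantile normalisation kept r = 0.9997 with it. The composition of the RNA, set by handling, batch or the animals' kidneys, may differ along it; these were not told apart, and no biological explanation was tested.

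The relations behind that pattern were 8 in all. For the share of the 10 most abundant genes, r with the component was -0.928 in anti-Fx1A (n = 10, permutation p = 0.00043, adjusted 0.00344; rho = -0.806, permutation p = 0.00706, adjusted 0.0282; r = -0.881 without the 2 farthest animals). It was -0.829 in the combination (permutation p = 0.00326, adjusted 0.013; rho = -0.915, permutation p = 0.00062, adjusted 0.00496; r = -0.899 without the farthest). In L-NAME r was -0.598 (permutation p = 0.0581, adjusted 0.116; rho = -0.648, permutation p = 0.0493, adjusted 0.0986; -0.669 without the farthest), and in vehicle 0.0499 (n = 8, permutation p = 0.894, adjusted 0.894; rho = 0.143, permutation p = 0.753; -0.199 without the farthest). For log2 depth in anti-Fx1A, the permutation p was 0.00526 (adjusted 0.014; rho = -0.673, permutation p = 0.0392, adjusted 0.0986; r = -0.821 without the farthest). The adjusted permutation p of r with depth was 0.763 in each of the other groups, where r was -0.195 in vehicle.

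Some genes had 0 reads in at least 1 animal of a group and at least 100 in another animal of the same group: 28 genes with vehicle, 35 with anti-Fx1A, 24 with L-NAME and 22 with the combination, 65 in all, of which 5 were of this kind in every group. ENSRNOG00000033152 and ENSRNOG00000029512 are among them, and 16 were called in the combination against vehicle. Counting error does not account for the zeros: over all genes with a mean of at least 10 reads in a group, which include these, 923 zeros were found where counting gives 0.752, a ratio of 1230. Of the 28 genes with vehicle, 67.9% were of this kind in a treated group, and 11, 12 and 12 recurred with anti-Fx1A, L-NAME and the combination, where independent lists would share at most 0.0486. Differences between animals that do not depend on the treatment may therefore account for these genes, and their calls between groups could reflect which animals fell into which group. Whether such differences are inherited, or go with a cohort or a batch that no label gives, stays open, as do reads that the authors' counting split between near-identical genes.

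The reads of ENSRNOG00000029512 followed the division of the anti-Fx1A animals on the second component: animals 9 to 12 had 418, 569, 218 and 131 reads, and animals 13 to 18 had 0, 0, 0, 35, 0 and 8. With L-NAME, animals 19 to 23 had 48 to 124 reads and animals 24 to 28 had 0. ENSRNOG00000033152 had 912 to 1945 reads in anti-Fx1A animals 9 to 12 and 145 to 963 in animals 13 to 18. Over all genes of this kind in anti-Fx1A, the number at 0 per animal was 3 to 13 in animals 9 to 12 and 8 to 16 in animals 13 to 18, ranges that overlap. These divisions were seen in the data and were not tested.

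Other assignments of the same animals to groups, 100 per comparison with the real one included, bear on chance. For anti-Fx1A, L-NAME and the combination against vehicle, and the combination against anti-Fx1A, 1 of 100 gave as many calls, the real one. The highest other counts were 89 against 139, 63 against 1780, 1425 against 4507 and 327 against 2428. With 100 assignments the share cannot fall under 1 in 100, so chance is made less likely but is not excluded. In the simulations without effects, 5 of 100 called any gene for anti-Fx1A against vehicle and 1 for L-NAME. The highest counts there were 573, above the real 139, and 615, below the real 1780. For anti-Fx1A the highest other count of 89 comes from the fit of all animals. The assignments were not repeated for the fits in which its count was 89 (without animal 12), 85 (without animal 15) or 50 (only these groups). None of these counts lies above 89. For the combination against L-NAME 4 of 100 gave at least the real 151, with a highest other count of 1013, and for anti-Fx1A against L-NAME 4 of 100 gave at least the real 48, with a highest other count of 1978. Both shares lie under the threshold of 0.05, but counts several times the real one point to a structure among the samples that the groups do not describe. For the interaction the real count is 0, which all 100 must reach, so they say nothing on chance there; the highest other count was 375.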

How the results depend on the processing

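The fits without 3 libraries, with covariates, with voom and with the same 4 vehicles were chosen after the data were seen. Counts of calls for L-NAME against vehicle, the combination against vehicle and the combination against anti-Fx1A stayed within 1.5 times their reported values in 11 of 12 alternatives, the exception being the 1.5-fold threshold. Leaving out animals in turn gave 1382 to 1960, 4068 to 4907 and 1668 to 2816 for these comparisons. The same animals left out gave 85 to 294 for anti-Fx1A against vehicle, 47 to 640 for the combination against L-NAME, 20 to 61 for anti-Fx1A against L-NAME and 0 to 15 for the interaction. L-NAME animal 25 gave the extremes of 640 and 20, and the cause was not tested.

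With the threshold of 1.5-fold, which by construction takes fewer genes, the counts were 36 for anti-Fx1A, 374 for L-NAME and 1373 for the combination against vehicle, 64 for the combination against L-NAME and 492 against anti-Fx1A, and 19 between the single treatments. Without the filter, which adds genes to the adjustment, the combination against L-NAME gave 95 and anti-Fx1A against L-NAME 27. The stricter filter gave 3 for the interaction. Fitting only the groups compared gave 50 for anti-Fx1A against vehicle and 22 against L-NAME. Library weights gave 624 for anti-Fx1A against vehicle, 990 for the combination against L-NAME and 37 for the interaction. Without 3 libraries the combination against L-NAME gave 1155 and the interaction 41, and with depth as a covariate the interaction gave 2. With the share of abundant reads as a covariate the counts were 260 for anti-Fx1A against vehicle, 341 for the combination against L-NAME, 77 between the single treatments and 4 for the interaction. The library weights, and through them the 3 libraries left out, were set by how far each library lay from its own group in these data. Narrowing the spread within groups is thus part of their construction. How much of the higher counts comes from this was not measured. Where no construction is named, the cause was not tested. The correlation of the single treatments fell from 0.779 to 0.470 with the vehicles split. It was 0.811 with the same 4 vehicles in both comparisons, so at 4 vehicles each the difference goes with the sharing. The spread of fewer shared vehicles also raises r. How much of the fall comes from the smaller number was therefore not measured. Leaving out animals moved the correlations within 0.27 to 0.445 for anti-Fx1A, 0.598 to 0.743 for L-NAME and 0.737 to 0.821 for the single treatments.

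Voom called 115, 1708 and 4296 genes against vehicle for anti-Fx1A, L-NAME and the combination, of which 113, 1683 and 4262 were the same genes. Of 591 values of the 4 genes under alternatives, 569 kept direction and side of the threshold, 13 were no longer called and 8 became called. The value that reversed was ENSRNOG00000033152 in anti-Fx1A against vehicle, which was not called in either fit, at 0.288 with voom in place of -0.30. Median-centring and quantile normalisation moved the share of higher calls by less than 10 percentage points in the 6 comparisons with calls. Set tests of gene lists, relations across animals and the named panel were not run, for want of gene names. No paired analysis was possible because no number or label pairs animals across groups. Depth limits what can be said of genes with few reads, whose fold changes the deposited scale compresses.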

Other observations

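The tests below were chosen after the correlations of fold changes had been seen. The animals compared in each test are not in the comparison that chose the genes, but they entered the filter and the estimate of the spread, so each test was repeated with genes filtered and called in a fit of the choosing groups alone.

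The 1780 genes called for L-NAME against vehicle were averaged in each animal as the mean of the higher genes minus that of the lower ones. This score was 0.00922 ± 0.141 in the combination and -0.563 ± 0.21 with anti-Fx1A alone (SD, n = 10 each), a difference of 0.573 log2 units (two-sided permutation p = 1e-05, the smallest that 100000 resamples give). It was higher than in any anti-Fx1A animal in 10 of 10 combination animals. The groups that chose the genes had -1.08 ± 0.0904 with vehicle (n = 8) and -0.168 ± 0.265 with L-NAME (n = 10). With the 1630 genes called in a fit of L-NAME and vehicle alone the difference was 0.595 (two-sided permutation p = 5e-05, 9 of 10 animals). The response to L-NAME may thus recur in the presence of anti-Fx1A.

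The score of the 139 genes called for anti-Fx1A against vehicle was 0.244 ± 0.103 in the combination and 0.00444 ± 0.121 with L-NAME alone (SD, n = 10 each), a difference of 0.24 (two-sided permutation p = 0.00017). It was higher than in any L-NAME animal in 9 of 10 combination animals. With the 50 genes called in a fit of anti-Fx1A and vehicle alone the difference was 0.44 (two-sided permutation p = 0.00037, 5 of 10 animals). The score is not particular to the antiserum: it was -0.928 ± 0.115 with vehicle (n = 8) and 0.0554 ± 0.228 with anti-Fx1A alone (n = 10), and L-NAME alone already stood near the latter. The rise from vehicle is inflated by the choice of the genes on those animals, so its size is not set against the gain over L-NAME. The correlation of the antiserum's fold changes without and with L-NAME, r = 0.352, lay inside the range without effects. Part of the response to the antiserum may recur at its lower dose, but these values do not separate it from a stronger response to L-NAME.

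The median SD of a gene between animals of a group was 0.224 log2 units with vehicle, 0.235 with anti-Fx1A, 0.227 with L-NAME and 0.218 with the combination. No gene had reads in every animal of a group and none in any animal of another (0 genes for each of the ordered pairs of groups).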
